A study of Mus musculus with 8 samples.

How the data were processed

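Dorsal skin of male mice was profiled on 8 Affymetrix expression arrays, 1 array for each of 8 labels. The labels name a genotype (WT, or KO for the IL-22 receptor alpha chain), whether imiquimod cream (IMQ) was in the label, and in some KO samples the letter B or alloferon. Per the labels, 83.3 mg of 5% IMQ cream was applied daily from day 1 to day 7, and vehicle or alloferon cream followed 6 hours later. The study states 4 mice per group. Whether RNA of several mice was pooled on an array is not given in the sources used here, and neither is the meaning of the letter B.

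The deposited values are log2 expression values for 41345 probe sets per array, which the authors made by robust multi-array averaging (RMA) in Affymetrix Power Tools, per the submitters' processing notes; R 3.3.2 is also named there without a role. RMA corrects background, puts all arrays on 1 common distribution and summarises the probes of a set. It compresses differences of dim genes, and a change shared by most genes is removed by it. The array medians differed by at most 0.05 log2 units. The number of arrays limits the precision; there is no count or sequencing depth. No array pair held identical values. All 8 value columns were matched to a label by name.

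Probe sets were named through the platform annotation. Of the probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none. Entrez identifiers of 23328 were matched to the RefSeq table of GRCm38.p6, and no symbol changed, so older symbols such as Il1f6 for IL-36 alpha remain. A gene with several probe sets (1082 genes) was represented by the one with the highest mean over the 8 arrays, which gave 22180 genes. No filter on dim genes was used.

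Tests used limma 3.58.1 in R 4.3.3 on the log2 values, with lmFit and eBayes and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05. An arm here is a pair of arrays whose labels differ in IMQ alone: WT plain, KO plain, KO B and KO Allo. The fit for separate genotypes had a level per arm, 1 IMQ effect for WT and 1 for KO, with 2 residual degrees of freedom. The fit for WT and KO together had a level per arm and 1 IMQ effect over the 4 pairs, with 3 residual degrees of freedom. The spread is thus how far the IMQ difference varies among pairs, and includes any true difference in response between arms. Since nothing says that the arrays hold separate animals, the p-values measure the spread between these arrays, which may be partly technical. Errors given with ± are standard errors from limma over the pairs, unless stated otherwise.

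Comparisons of 1 array with 1 have no replicate check. For these, genes differing by 1 log2 unit or more (2-fold) were counted, and the median of a gene list was placed among 10000 random lists of the same size matched on mean level, without a p.

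Before the data were examined, 32 gene lists of pathways, cell types and skin structures were fixed, together with the comparisons, the alternatives and the rule for named genes. The rule takes the 10 highest and 10 lowest log2 differences among called genes with the same sign in every pair. Where fewer pass, it takes the genes with the smallest unadjusted p up to 10 per direction, as values only. For 1 array against 1 it takes the 10 largest differences each way among genes whose higher array lies above the median level. It adds the members of the IL-22 receptor list and up to 4 members per gene list, those with the largest size of difference. Where 5 or fewer members of a list passed a test, those outside the rule are named as well, a choice made after their values were seen. Clone-type symbols, olfactory receptors, and immunoglobulin and T cell receptor segments were left out. A list needed 3 measured members, which left 31. Red blood cells, with 1 measured member, were not tested. Lists were tested with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated per list. With the estimate, 0 lists passed in any comparison, so every list call below holds only with the preset. The estimate rests on 2 or 3 residual degrees of freedom, so that test has little power. A list that does not pass it is therefore not shown to be unshifted.

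The fits were tested on simulated data with 200 changed genes among 22180. For WT and KO together, the fit recovered 76% of genes changed by 1 log2 unit, 96% at 2 and 99% at 3. For KO it recovered 0% at 1 log2 unit, 92% at 2 and 97% at 3. For WT it recovered 0%, 69.5% and 94%. Each changed gene was given the same shift on every IMQ array, so these shares leave out responses that vary between pairs. On the measured arrays 0 genes passed for KO, although Serpinb3a measured 4.66 log2 units over the KO pairs. A missing call thus does not show that changes of 2 or 3 log2 units were absent. In the simulated camera test for WT and KO together, 50 of 50 lists of 15 genes shifted by 0.7 log2 units were called, and 3 of 50 unshifted lists were called. The simulated genes were drawn independently of each other, and a list was called there at an unadjusted p under 0.05. The 3 of 50 is thus no false call rate for lists of genes that vary together, as those used below may.

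The alternatives were a trended robust prior, median centring of each array, a second quantile normalization, removal of dim probe sets, the mean of a gene's probe sets, a fold threshold, fits without arm levels, other sets of arrays, each array left out in turn, and reading the letter B as a second array of the same label. After the data were seen, a muscle or hair follicle covariate (the mean of that list on each array), the removal of pairs, and 3 tests on alloferon were added. Those 3 tests read B as a second array and had 2 residual degrees of freedom. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.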

Results

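Imiquimod, a Toll-like receptor agonist, induces psoriasis-like inflammation when applied to mouse skin. The series asks how the skin's response to it depends on the IL-22 receptor, a cytokine receptor of epithelial cells, and on alloferon, a peptide first described in insects. Arrays were labelled WT_CTRL, WT_IMQ, KO_CTRL, KO_IMQ, KO_CTRL-B, KO_IMQ_B, KO_Allo and KO_IMQ_Allo, with 1 array each. On the first principal component, which held 46.8% of the variance, the 4 IMQ arrays lay between 21.5 and 37.8. The WT_CTRL, KO_CTRL and KO_CTRL-B arrays lay at -42.5, -28.6 and -33.2, and KO_Allo lay at -7.03. Between arrays that share the IMQ status, 203 to 699 genes differed by 1 log2 unit or more (median 292 over 12 array pairs). Between arrays of different status, 344 to 1220 genes did (median 895 over 16).

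Il22ra1, which encodes the targeted receptor chain, was not lower on the arrays labelled KO. Its single probe set read 8.23 on WT_CTRL and 8.64 on WT_IMQ, against a mean of 8.93 ± 0.26 (SD, n = 6) on the arrays labelled KO, whose range was 8.59 to 9.40. A probe set for the whole transcript need not cover the altered part of the gene, so this level does not check the genotype. The strain label names a targeted Il22ra1 allele. Whether that allele is conditional, and in which cells it was deleted, is not given in the sources used here, so KO is used as the labels use it. Every direction given below between WT and KO rests on the labels.

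The first comparison asks what IMQ changed over all 4 pairs of arrays. The largest rises were those of Sprr2d and S100a8. Sprr2d, a cornified envelope protein, rose by 5.41 ± 0.56 log2 units (adjusted p = 0.0149), and S100a8, which encodes a subunit of the alarmin calprotectin, rose by 5.34 ± 0.47 (adjusted p = 0.0124). Csta3 rose by 5.02, Serpinb3a by 4.79, S100a9 by 4.70, Lce3f by 4.31, Krt16 by 4.30, Sprr2e by 4.24, Rptn by 4.19 and Sprr1b by 3.95 log2 units. The largest falls included genes of the hair follicle. Krtap8-1 changed by -4.18 log2 units, the inner root sheath genes Tchh, Krt71, Krt27, Krt26 and Krt25 by -3.64, -3.48, -3.42, -3.36 and -3.05, and Krtap1-5 by -3.25. Mrgprb3, Lyg2 and Dapl1 changed by -3.63, -3.34 and -2.90. In limma, 421 genes rose and 264 fell among 22180, and all 685 had the same sign in 4 of 4 pairs, which a call over these pairs favours; of all genes 27.0% did, where chance gives 12.5%. Of these, 199 rose and 102 fell by 1 log2 unit or more. The unadjusted p was under 0.05 for 4171 genes, where chance gives 1109. The count depends on the pairs used: it was 0 without WT_CTRL or WT_IMQ, 2 without KO_CTRL-B or KO_IMQ_B, 260 without KO_CTRL or KO_IMQ and 1307 without KO_Allo or KO_IMQ_Allo, each of which removes the pair from the estimate. It was 0 with either the muscle or the hair follicle covariate, each added after the data were seen, and 72 without the plain pairs.

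By gene group, the injury-induced cornified envelope list rose in 12 of 18 measured members over all genes tested and in 16 adjusted over the list alone. Its largest rises were those of Sprr2d, Lce3f, Sprr2e and Sprr1b given above, and the list median was 2.69 (adjusted p = 0.265 with an estimated correlation). Antimicrobial and alarmin genes rose in 8 of 14 (9 adjusted over the list alone), among them S100a8, S100a9 and Defb3, a beta-defensin, the last by 3.53 ± 0.44. The serum amyloid gene Saa3 measured 3.66 ± 0.85 (adjusted p = 0.0743). The IL-1 and IL-36 family rose in 6 of 10 (8 adjusted over the list alone). IL-36 alpha, beta and gamma, annotated as Il1f6, Il1f8 and Il1f9, rose by 3.27 ± 0.22, 2.44 ± 0.25 and 2.47 ± 0.21 log2 units. Il1b measured 1.94 ± 1.14 (adjusted p = 0.420). Among the hyperproliferation-associated keratins, Krt16 alone of 4 passed over all genes, and 3 rose adjusted over the list alone (Krt6b, Krt16 and Krt6a). Krt6b measured 5.24 ± 1.18 (adjusted p = 0.0676). Homeostatic epidermal differentiation genes were split: 4 of 17 rose (Casp14, Asprv1, Dsc1 and Cdsn, by 1.33, 0.98, 0.75 and 0.69), and adjusted over the list alone 11 rose and 2 fell (Krt77 and Flg2). Krt77 measured -4.28 ± 0.88 and Flg2 -1.89 ± 0.38 (adjusted p = 0.0566 and 0.0529). The camera test called all of these lists upward, and each had an adjusted p = 0.265 with an estimated correlation. The keratin and homeostatic differentiation calls were lost with the muscle covariate, and the IL-1 and IL-36 call with the hair follicle covariate.

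Among immune cell lists, monocyte and macrophage genes rose in 4 of 13 (9 adjusted over the list alone). Adgre1, which encodes the macrophage marker F4/80, rose with an adjusted p = 0.0157, Arg1 by 1.79 ± 0.34, Csf1r by 0.95 ± 0.18 and Lyz2 by 0.85 ± 0.13 log2 units. Neutrophil genes rose in 2 of 14, the chemokine receptor gene Cxcr2 by 1.99 ± 0.29 and Fpr2 by 1.33 ± 0.22, and with Csf3r and Mmp8 4 rose adjusted over the list alone. In the IL-23 and IL-17 list Il23r alone of 12 rose, by 1.34 ± 0.21, and 5 rose adjusted over the list alone, with Il17f at 0.74 ± 0.20, Il17rc at 0.48 ± 0.10, Il17ra at 0.42 ± 0.10 and Il17a at 0.42 ± 0.14. In the IL-22 receptor list 1 of 11 rose, the shared receptor chain gene Il10rb, by 0.81 ± 0.15 (adjusted over the list alone Il10rb, Il20 and Stat3, 3 genes, rose and 1, Il20ra, fell). The others of that list measured 0.29 (Il22ra1), -0.54 (Il22ra2), -1.82 (Il20ra), -0.11 (Il20rb), 0.16 (Il22), 0.67 (Il19), 0.54 (Il20), 0.42 (Il24), 0.47 (Stat3) and 0.56 (Socs3). NF-kB and TNF response genes rose in 1 of 11, Nfkbiz, by 0.61 ± 0.10 (3 adjusted over the list alone, with Birc3 and Nfkbia). These 5 lists and the T cell list (0 of 13, and 1, Cd4, adjusted over the list alone) were called upward by camera, each with an adjusted p = 0.265 with an estimated correlation. The IL-22 receptor, IL-23 and IL-17, and neutrophil calls were lost without dim probe sets, and the IL-22 receptor and T cell calls without KO_Allo or KO_IMQ_Allo. The IL-22 receptor, neutrophil, T cell and macrophage calls were also lost with the muscle and with the hair follicle covariate. The muscle covariate lost the IL-23 and IL-17 call as well, and the hair follicle covariate the NF-kB call. Endothelial genes (0 of 8, list median 0.28) were also called upward, with an adjusted p = 0.674 with an estimated correlation. That call was lost without dim probe sets and without any array of the WT, KO plain or KO B pairs.

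Lists for other skin structures held genes that fell. Hair follicle genes fell in 16 of 21 (20 adjusted over the list alone), with a list median of -2.30. Krt27 changed by -3.42 ± 0.34 and Krt25 by -3.05 ± 0.36. Melanocyte genes fell in 5 of 6 (6 adjusted over the list alone), including the pigment enzyme genes Tyr (-1.60 ± 0.24), Tyrp1 (-1.57 ± 0.23) and Dct (-1.49 ± 0.18), as well as Pmel (-1.27 ± 0.22) and Slc45a2 (-1.12 ± 0.22). Sebaceous gland and skin lipid genes fell in 3 of 13 (8 adjusted over the list alone): Mc5r (-1.33 ± 0.18), Fads2 (-1.13 ± 0.14) and Awat2 (-0.82 ± 0.14). Skeletal muscle genes fell in 3 of 15 (14 adjusted over the list alone): Actn3 (-2.32 ± 0.45), Myh1 (-1.09 ± 0.19) and Mb (-1.07 ± 0.17). Adipocyte genes fell in 1 of 11, Car3 (-1.02 ± 0.19), and in 5 adjusted over the list alone (Lep, Car3, Fabp4, Retn and Lpl). These 5 lists were called downward by camera; with an estimated correlation the adjusted p was 0.370 for adipocytes and 0.265 for the others. Tissue content differed between arrays without IMQ as well. The muscle list median was 11.19 on WT_CTRL and 11.33 on KO_CTRL, against 7.84 to 9.30 on the other 6 arrays, and the hair follicle list median was 9.67 on WT_CTRL, 10.10 on KO_CTRL-B, 8.92 on KO_Allo and 6.74 on KO_CTRL.

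No shift passed for the type I interferon list (0 of 20, median -0.04), the interferon gamma list (0 of 15, median 0.02 and an upward test direction with a mean just below 0), NK and cytotoxic cells (0 of 14, median -0.03), B and plasma cells (0 of 7, -0.08), dendritic and Langerhans cells (0 of 10, -0.07), mast cells (0 of 8, 0.53), neutrophil chemoattractants (0 of 8, 0.35), the cell cycle (0 of 21, 0.08), fibroblasts (0 of 11, median 0.08 with a downward test direction), Schwann cells (0 of 4, -0.15) and the circadian clock (0 of 12, -0.15). In each of these lists 0 members passed adjusted over the list alone. Mast cells and neutrophil chemoattractants gained a call without KO_Allo or KO_IMQ_Allo, and the cell cycle, Schwann cell and circadian clock lists without WT_CTRL or WT_IMQ. Fibroblasts gained one without the plain pairs and with either covariate, the cell cycle also without the plain pairs, and the type I interferon, mast cell, immediate early, cell cycle, Schwann cell and circadian clock lists with the hair follicle covariate. Among immediate early genes 1 of 12 rose, Ier3, by 0.85 ± 0.16 (also 1 adjusted over the list alone, list median 0.08, no shift called). In the basal epidermis list 1 of 8 fell, Krt15 (-1.56 ± 0.25), and adjusted over the list alone 1 fell and 1 rose, Krt14 (list median -0.01, no shift called). Of 12 genes neighbouring Il22ra1, 1 rose, the epidermal regulator gene Grhl3, by 1.11 ± 0.10, and adjusted over the list alone 2 rose and 1 fell (Grhl3, Cnr2 and Ifnlr1). That list had a median of -0.14, a mean of 0.01 and a downward test direction, with no shift called. Slc4a1, the red blood cell gene that was measured, measured -0.35 ± 0.17.

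**Figure D1:**
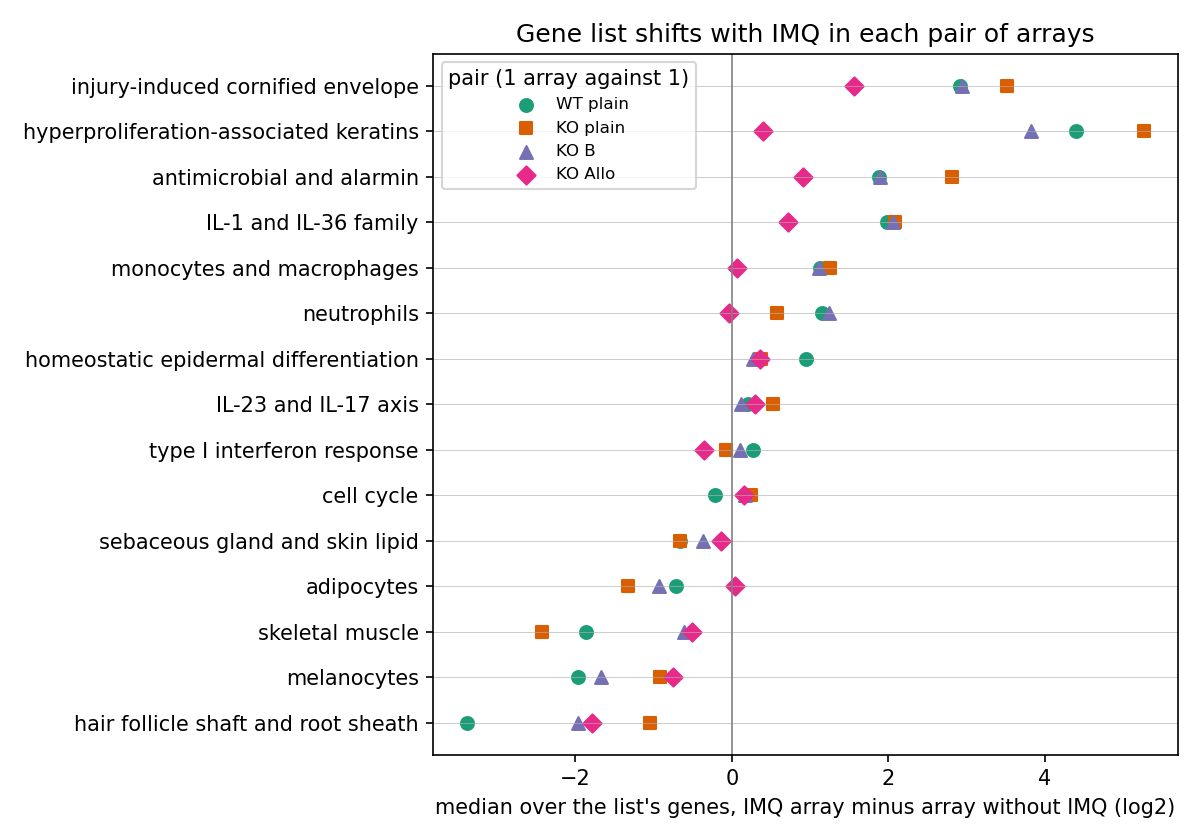
Each point is the median, over the genes of a list, of the IMQ array minus the array without IMQ (x axis, log2 units), for 15 gene lists (y axis) and the 4 pairs WT plain, KO plain, KO B and KO Allo (1 array against 1, no error bars). The hair follicle list lies between -3.38 and -1.05 in all 4 pairs, and the keratin list reads 0.39 in the KO Allo pair against 3.82 to 5.26 in the others.

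The second comparison asks what IMQ changed on the KO arrays. Among the 10 genes with the smallest p in each direction, Il1f6 and Il1f9 measured 3.05 ± 0.21 and 2.21 ± 0.16 log2 units, Lcn2 2.33 ± 0.15, Serpinb3a 4.66 ± 0.41 and S100a9 4.64 ± 0.45, and the hair follicle genes Dsg4, Krt75 and Hoxc13 measured -2.34 ± 0.14, -1.54 ± 0.13 and -1.30 ± 0.12 (n = 3 pairs). Others were Serpinb3d, Sdr9c7, Alox12b, Cyp3a13 and Grhl3, higher with IMQ, and Car6, Sytl2, Gabrp, Tmem64, Samd5, Slc39a10 and Slc9a2, lower with IMQ. 0 genes passed in limma, where the smallest adjusted p was 0.0649 (Dsg4), and the unadjusted p was under 0.05 for 3093 genes. Adjusted over the list alone, 15 of 18 cornified envelope genes, 9 of 14 antimicrobial genes, 7 of 10 IL-1 and IL-36 genes, 7 of 13 macrophage genes and 4 of 4 keratins rose, and 20 of 21 hair follicle genes, 13 of 15 muscle genes and 6 of 6 melanocyte genes fell. Camera called 12 lists upward and 7 downward; the smallest adjusted p was 0.402 with an estimated correlation. The count of called genes was 50 with a trended robust prior, 58 without arm levels, 152 with the letter B read as a second array and 148 for the plain pair alone, where 1 array is set against 1 with the spread from the KO B and KO Allo pairs. It was 72 without KO_CTRL or KO_IMQ and 299 without KO_Allo or KO_IMQ_Allo.

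The third comparison asks the same of the WT pair, with the spread taken from the KO pairs. Il1f6 measured 3.94 ± 0.36 and Il1f9 3.24 ± 0.27 log2 units, Serpinb12 3.49 ± 0.32 and Lce1g 2.07 ± 0.20, against -3.78 ± 0.23 for Dsg4, -3.48 ± 0.29 for Krt35 and -5.19 ± 0.50 for Lyg2. In limma 0 genes passed (smallest adjusted p 0.174, 2396 genes with an unadjusted p under 0.05). Adjusted over the list alone, 11 of 18 cornified envelope genes, 6 of 14 antimicrobial genes and 6 of 10 IL-1 and IL-36 genes rose, and 19 of 21 hair follicle genes fell. Camera called 12 lists upward and 6 downward, including mast cells (median 1.62) upward; with an estimated correlation the smallest adjusted p was 0.444. The count was 1 with a trended robust prior and 1 with B read as a second array, 41 without KO_CTRL or KO_IMQ, and 29 without KO_Allo or KO_IMQ_Allo.

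The fourth comparison asks whether the response to IMQ differed between WT and KO. Of the 200 genes with the smallest p over the KO pairs, 198 moved in the same direction in the WT pair, with a slope of 1.19 of WT on KO. Across all genes, which are not independent replicates, the correlation of the 2 responses was r = 0.727. In limma 0 genes differed (smallest adjusted p 0.983, 914 genes with an unadjusted p under 0.05, where chance gives 1109), and all alternatives run gave 0. Among the genes with the smallest p were values of 1.48 ± 0.22 log2 units for Otop3, higher in WT, and -1.52 ± 0.23 for Myoz2. By list, the WT response was higher for mast cells (median difference 1.36), the IL-1 and IL-36 family (0.70), endothelium (0.68) and the type I interferon response (0.45), and lower for hair follicle genes (-1.02) and melanocytes (-0.84). With an estimated correlation the adjusted p was 0.503 for hair follicle genes and 0.681 for the others named. The KO Allo pair enters the KO side: the IL-1 and IL-36 median was 1.99 in the WT pair against 2.08, 2.06 and 0.71 in the KO plain, B and Allo pairs, and that of mast cells 1.62 against 0.37, 1.04 and -0.63. Camera called 7 lists upward and 6 downward, and 0 members passed adjusted over the list alone. The antimicrobial list (median 0.13, mean -0.08, downward) and the cornified envelope list (median 0.02, mean -0.01, downward) were among those not called. A p over the threshold does not show that the responses are alike.

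The fifth comparison sets the KO plain pair against the WT pair, averaged over IMQ status. Lcn2 measured 1.67 ± 0.18 log2 units and the solute carrier gene Slc6a14 1.47 ± 0.18, and the sebaceous genes Awat1 and Dgat2l6 both measured 1.39, higher in KO. The hair follicle genes Dsg4 and Krt35 measured -1.49 ± 0.17 and -1.43 ± 0.21. In limma 0 genes passed (smallest adjusted p 0.742, 1351 with an unadjusted p under 0.05), and 11 were lower without KO_IMQ. Adjusted over the list alone, 12 of 21 hair follicle genes and 5 of 6 melanocyte genes (Tyr, Tyrp1, Pmel, Slc45a2 and Dct) were lower in KO, and 6 of 13 sebaceous genes were higher and 1 (Fads2) lower. Camera called 8 lists upward and 4 downward. The hair follicle median was -1.43 (adjusted p = 0.506 with an estimated correlation), from -2.31 without IMQ and -0.41 with IMQ, and the sebaceous median 0.58 (adjusted p = 0.643 with an estimated correlation). The KO B arrays are not in this comparison. Their hair follicle medians lay above WT (10.10 against 9.67 without IMQ, 7.65 against 6.33 with IMQ). Their melanocyte medians did too (8.67 against 8.40 and 7.01 against 6.65), and their sebaceous medians lay just below WT (9.36 against 9.50 and 8.74 against 8.78). These differences between KO and WT thus do not hold for all KO arrays.

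On single arrays without IMQ, hair genes were among those furthest lower on KO_CTRL than on WT_CTRL. Krtap22-2 read 4.16 against 9.33 and Krtap8-1 5.48 against 10.33, while Serpinb6d read 10.57 against 8.31 and the interferon-induced Ifit1 6.92 against 5.48. The other KO array without IMQ or alloferon, KO_CTRL-B, went the other way, with 10.81 for Krtap22-2, 11.33 for Krtap8-1 and 6.25 for Serpinb6d. By 1 log2 unit or more, 99 genes were higher and 198 lower on KO_CTRL than on WT_CTRL. The hair follicle list median was -2.31 (percentile 0 among random lists) and the type I interferon list median 0.36 (percentile 100). Melanocytes (-1.66) and the cell cycle (-0.54) were also at percentile 0, sebaceous genes (0.50) at percentile 100 and mast cells (0.34) at percentile 99.8. The IL-1 and IL-36 family (0.44) lay at percentile 100, and adipocytes (0.35) and muscle (0.29) also lay high. With IMQ, KO_IMQ minus WT_IMQ had 158 genes higher and 129 lower. Uox read 8.82 against 5.59, Alox8 9.37 against 6.62 and Lcn2 9.08 against 6.71, and the cornified envelope and antimicrobial medians were 0.94 and 1.18 (percentile 100 for both). Krt71 read 4.59 against 7.87, and the mast cell median was -0.73 and the type I interferon median -0.32 (percentile 0 for both), opposite in sign to those without IMQ. Adipocytes (-0.39, also opposite in sign), fibroblasts (-0.32), endothelium (-0.38) and hair follicle genes (-0.41) read lower as well, and the IL-23 and IL-17 list read higher (0.37, 12 of 12 members). These differences have no replicate check, and the KO B arrays had the same direction for some list medians only. Without IMQ, KO_CTRL-B read 6.17 against 5.64 on WT_CTRL for type I interferon genes, also higher. Its mast cell median was lower, at 5.14 against 5.46. With IMQ, KO_IMQ_B kept the direction against WT_IMQ for antimicrobial genes (8.16 against 7.62), the cornified envelope (8.81 against 8.37) and mast cells (6.43 against 7.35). For type I interferon genes it read 6.34 against 6.21, the other way.

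The next comparison concerns alloferon on IMQ-treated KO skin. On KO_IMQ_Allo, several inflammatory genes read lower than on KO_IMQ_B. Il1b, which encodes the cytokine IL-1 beta, read 4.78 against 8.68, the chemokine genes Ccl3 and Cxcl2 4.86 against 8.39 and 4.92 against 7.97, Ptgs2, the inducible cyclooxygenase, 5.51 against 8.81, Acod1 4.13 against 7.56 and the collagenase gene Mmp13 4.23 against 7.74. Cyp2b23 read 7.25 against 4.62, Alox8 10.12 against 8.39 and Krt77 8.21 against 6.55. By 1 log2 unit or more, 111 genes were higher and 171 lower. The medians were -1.26 for neutrophil chemoattractants, -0.70 for macrophages, -0.54 for neutrophils, -0.53 for mast cells, -0.46 for type I interferon genes and -0.43 for antimicrobial genes (percentile 0 for each), against -0.01 for the IL-1 and IL-36 family (percentile 59.1) and 0.24 for the IL-23 and IL-17 list (percentile 99.6, with 9 of 12 members higher), -0.75 for hair follicle genes and 0.53 for sebaceous genes. The circadian clock median was 0.44 (percentile 100). Against KO_IMQ_B the total was 282 genes and against KO_IMQ 329, where arrays of the same IMQ status had a median of 292. Against KO_IMQ, 150 genes were higher and 179 lower. Il1b, Saa3, Mmp13 and Tmprss11g differed by -3.11, -3.06, -2.92 and -2.88 log2 units, and the hair genes Krt71, Tchh and Krt25 read 8.66 against 4.59, 7.98 against 5.04 and 7.97 against 5.19. The medians against KO_IMQ were -1.14 for the cornified envelope, -0.71 for antimicrobial genes, -0.66 for macrophages and -0.54 for neutrophils (percentile 0 for each), -0.25 for the IL-1 and IL-36 family (percentile 0.56), -0.47 for neutrophil chemoattractants, -0.086 for the IL-23 and IL-17 list and 0.36 for the circadian clock (percentile 100). Other tissue lists differed as well, with 0.99 for melanocytes, 0.66 for sebaceous genes, 0.63 for hair follicle genes (opposite in sign to that against KO_IMQ_B), -0.53 for muscle and -0.48 for endothelium. Both comparisons share the KO_IMQ_Allo array, so a deviation of that array appears in both. KO_IMQ_B and KO_IMQ, both without alloferon, differed as well. For KO_IMQ_B minus KO_IMQ the medians were -0.51 for antimicrobial genes and -0.59 for the cornified envelope (percentile 0 for both). They were 0.79 for neutrophil chemoattractants and 0.36 for type I interferon genes (percentile 100 for both) and 0.26 for macrophages (percentile 99.97). Neutrophils (0.07) and mast cells (0.02) differed less.

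With the letter B read as a second array, a test added after the data were seen, KO_IMQ_Allo could be set against both other KO IMQ arrays. The alloferon side is 1 array, assumed to vary as the plain and B arrays differ from each other, and KO_CTRL-B and KO_CTRL alone differed in 631 genes by 1 log2 unit or more. In limma 0 genes passed (smallest adjusted p 0.779, 1271 with an unadjusted p under 0.05). Camera called 3 lists upward and 10 downward, among them macrophages (median -0.61, with 2 of 13, Cd14 and Msr1, lower adjusted over the list alone), neutrophil chemoattractants (median -0.86, with 4 of 8, Ccl3, Cxcl3, Cxcl2 and Ccl4) and neutrophils (median -0.61, with 2 of 14, Clec4d and Csf3r). Each of these had an adjusted p = 0.462 with an estimated correlation. Sebaceous genes (median 0.65, with 1 of 13, Scd3, higher adjusted over the list alone) were called upward, also with an adjusted p = 0.462 with an estimated correlation.

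**Figure D2:**
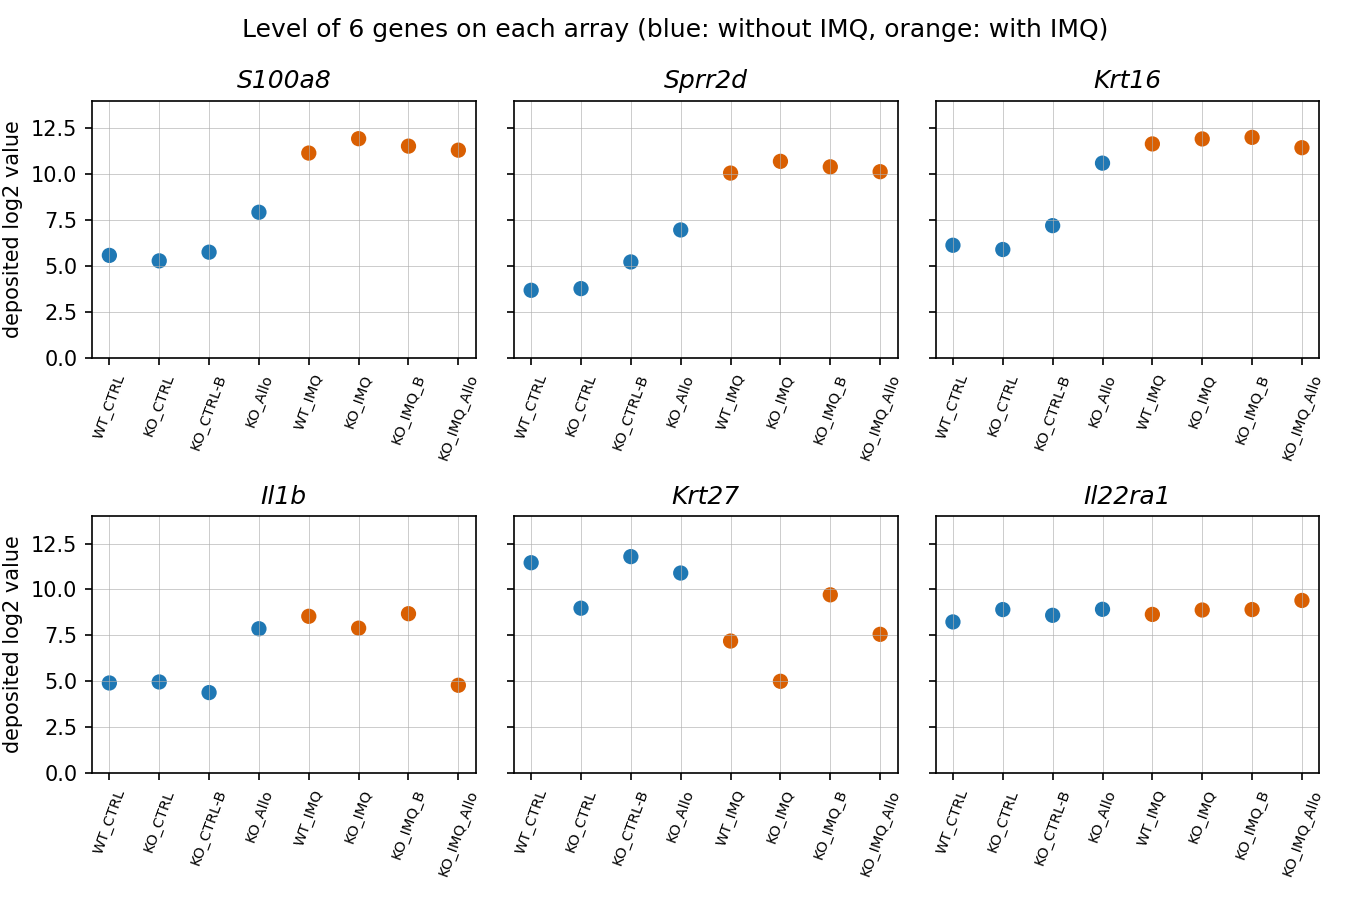
Each point is the deposited log2 value (y axis) of S100a8, Sprr2d, Krt16, Il1b, Krt27 or Il22ra1 on 1 of the 8 arrays (x axis), with IMQ in orange and without IMQ in blue. Il1b reads 7.86 on KO_Allo and 4.78 on KO_IMQ_Allo, while S100a8 reads 7.92 and 11.30 on the same arrays.

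The last comparisons set the KO arms against each other, averaged over IMQ status. Alloferon minus B gave 1.33 ± 0.14 log2 units for Nradd and -2.30 ± 0.33 for Rabggtb. In limma 0 genes passed (smallest adjusted p 0.975, 980 with an unadjusted p under 0.05), and camera called 3 lists upward and 3 downward. The number and balance of these list calls changed when 1 array was left out, most without KO_CTRL-B, KO_Allo or KO_IMQ_Allo. Hair follicle genes had a median of -1.07 (adjusted p = 0.753 with an estimated correlation), and type I interferon genes -0.34 and sebaceous genes 0.46 (adjusted p = 0.754 with an estimated correlation for both). Of the 13 sebaceous genes 3 (Elovl6, Awat2 and Awat1) were higher adjusted over the list alone. Alloferon minus plain gave 1.74 ± 0.14 for Olah, 1.56 ± 0.17 for Dsg4 and -1.32 ± 0.17 for the immediate early gene Fos, with 0 genes passing in limma (smallest adjusted p 0.610, 1540 with an unadjusted p under 0.05) and 88 without KO_IMQ. For this difference 11 of 21 hair follicle genes and 4 of 6 melanocyte genes (Pmel, Tyr, Tyrp1 and Dct) were higher and 8 of 15 muscle genes lower adjusted over the list alone, with list medians of 1.19, 0.89 and -1.32; with an estimated correlation the adjusted p was 0.356 for the first and 0.625 for the other lists named. Camera called 6 lists upward and 5 downward. Among these arm comparisons B minus plain gave the largest hair differences. Dsg4 measured 2.59 ± 0.17, Krt35 2.51 ± 0.21 and Lyg2 3.85 ± 0.35, and the hair follicle median was 2.51, with 20 of 21 members higher adjusted over the list alone (adjusted p = 0.349 with an estimated correlation). The muscle median was -1.20 (adjusted p = 0.766 with an estimated correlation), and camera called 5 lists upward and 5 downward. For B minus plain 0 genes passed in limma (smallest adjusted p 0.216, 1498 with an unadjusted p under 0.05), 135 without KO_IMQ, and 1 without KO_Allo or KO_IMQ_Allo.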

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

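The tests of alloferon in this part were chosen after the data were seen. The response to IMQ differed between WT and KO for 13 gene lists in camera's test of the difference itself, with 0 genes called. The median WT minus KO difference was 1.36 for mast cells, 0.70 for the IL-1 and IL-36 family, 0.68 for endothelium, 0.45 for type I interferon genes, 0.37 for fibroblasts, 0.35 for macrophages and 0.35 for homeostatic epidermal differentiation. It was -0.19 for immediate early genes, -0.35 for the cell cycle, -0.45 for sebaceous genes, -0.75 for muscle, -0.84 for melanocytes and -1.02 for hair follicle genes. With an estimated correlation 0 of these lists passed. The WT side of this difference is 1 pair of arrays, and the KO side includes the KO Allo pair: the macrophage median was 1.13 in the WT pair against 1.25, 1.11 and 0.061 in the KO plain, B and Allo pairs. Muscle genes measured -1.87 in the WT pair against -2.42, -0.61 and -0.51, lower in the KO plain pair than in WT, and sebaceous genes -0.67 against -0.66, -0.37 and -0.14.

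The response to IMQ also differed between the KO arrays with and without alloferon for 16 gene lists, with B read as a second array and 0 genes called in limma (smallest adjusted p 0.351, 1212 genes with an unadjusted p under 0.05). The median difference, with alloferon minus without, was -3.97 for the hyperproliferation-associated keratins, -1.61 for the injury-induced cornified envelope, -1.46 for neutrophil chemoattractants, -1.44 for antimicrobial genes, -1.42 for mast cells, -0.94 for macrophages, -0.87 for neutrophils and -0.62 for the IL-1 and IL-36 family. It was -0.53 for endothelium, -0.42 for fibroblasts and -0.26 for type I interferon genes. It was 0.22 for dendritic cells, 0.30 for NK and cytotoxic cells, 0.36 for sebaceous genes, 0.99 for muscle and 1.19 for adipocytes. With an estimated correlation 0 of these lists passed, and the smallest adjusted p was 0.326. Adjusted over the list alone, Il1b (-6.69 ± 0.57), Saa3 (-5.02 ± 0.57) and Sprr1b (-3.62 ± 0.23) were among the members that differed. The difference rests on KO_Allo and KO_IMQ_Allo, 1 array each, with the spread taken from the differences between plain and B arrays, and a high reading on the first counts as much as a low reading on the second.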

How the results depend on the processing

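The covariates, the removal of whole pairs and the alloferon tests with B as a second array were chosen after the data were seen, and the cause of a moved value was not tested unless named. For IMQ in KO the main count of 0 became 50 with a trended robust prior, 58 without arm levels, 148 for the plain pair alone and 152 with B read as a second array, and ranged from 0 to 299 with 1 array left out. For IMQ in WT it became 1 with that prior and 1 with B as a second array, and ranged from 0 to 41. For WT and KO together the 685 became 1049 without dim probe sets, 301 when 1 log2 unit was also required, 1307 without the KO Allo pair and 72 without the plain pairs, and ranged from 0 to 1307. It became 0 with the muscle or the hair follicle covariate, and the median standard error went from 0.112 to 0.234 and 0.472 log2 units. The range was 0 to 11 for KO minus WT, 0 to 88 for alloferon minus plain and 0 to 135 for B minus plain; leaving out 1 array drops its pair from the IMQ estimate. Between single arrays, removing dim probe sets and counting from 1.5-fold gave 160 and 1422 genes for KO_IMQ_Allo minus KO_IMQ_B, 195 and 1571 for KO_IMQ_Allo minus KO_IMQ, 191 and 1475 for KO_CTRL minus WT_CTRL, and 160 and 1460 for KO_IMQ minus WT_IMQ.

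List calls fell to 0 in all 8 planned comparisons with an estimated correlation, and from 17 to 7 for IMQ over all pairs with the muscle covariate. With 1 array left out they ranged from 6 to 17 for alloferon minus B and from 11 to 17 for alloferon minus plain. With the muscle covariate the list median turned to 0.041 for adipocytes and -0.10 for endothelium; that of muscle went to -0.0088, keeping its sign while the direction of its test turned. With the hair follicle covariate they were -0.25 for homeostatic differentiation, 0.46 for hair follicle genes, -0.69 for endothelium (called downward, adjusted p = 0.0132) and 0.49 for melanocytes. Without the plain pairs the T cell and endothelial calls were lost. The IL-22 receptor, neutrophil, T cell, macrophage and sebaceous calls were lost with each covariate. The muscle covariate also lost the IL-23 and IL-17, keratin and homeostatic differentiation calls. The IL-1 and IL-36, NF-kB and muscle calls were lost with the hair follicle covariate. Reversed genes with that covariate were Krtap8-1 (1.96), Lyg2 (1.48), Krtap1-5 (0.79), Arg1 (-0.014), Asprv1 (-0.13), Krt31 (0.46), Krt32 (0.70), Krt33a (1.48), Krt35 (1.24), Krt83 (1.31), Padi3 (0.79), Hoxc13 (0.25), Msx2 (0.73), Myh1 (0.071), Mb (0.081), Tyrp1 (0.38), Pmel (0.60), Tyr (0.32) and Slc45a2 (0.67). Each covariate is built from the genes of its own list, so its values for those genes are not an independent check. Of the 81 genes followed over all pairs, 20 lost their call with a trended robust prior, 5 with median centring, 3 with a second quantile normalization, 31 without arm levels, 80 without a WT array, 78 without a KO B array, 37 without a KO plain array and 3 without a KO Allo array. With the muscle covariate 80 lost their call, and with the hair follicle covariate 61 did and 19 reversed. Without the plain pairs 61 lost it. B could not be read as a second array for alloferon minus B or B minus plain, and comparisons with WT could not be fitted without a WT array.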

Other observations

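Apart from the counts over splits of the samples, the tests in this part were chosen after the data were seen. On KO_Allo, the array with alloferon and no IMQ, some genes raised by IMQ in other pairs read higher than on both other KO arrays without IMQ. Krt6b read 11.83 against 7.49 on KO_CTRL-B and 4.67 on KO_CTRL, Krt16 10.59 against 7.19 and 5.89, and Il1b 7.86 against 4.39 and 4.96. Lists of other cell types differed on the same array: against KO_CTRL-B and KO_CTRL, the medians were 1.16 and 0.66 for mast cells, -0.60 and -1.58 for adipocytes, and -0.36 and -2.26 for muscle. With B read as a second array, KO_Allo is 1 array whose spread is taken from the differences between plain and B arrays. By that test 0 genes passed in limma (smallest adjusted p 0.168, for Sprr1b, 1062 genes with an unadjusted p under 0.05). Camera called 10 lists upward and 4 downward. Among the hyperproliferation-associated keratins 3 of 4 (Krt6b, Krt16 and Krt6a) were higher adjusted over the list alone (list median 3.34, adjusted p = 0.506 with an estimated correlation), as were 5 of 10 IL-1 and IL-36 genes (Il1b, Il33, Il1a, Il1f8 and Il1f5) while 1 was lower, Il1r2 (median 0.76, adjusted p = 0.471 with an estimated correlation), and 4 of 14 neutrophil genes, Clec4d, Trem1, Csf3r and Cxcr2 (median 0.30, adjusted p = 0.471 with an estimated correlation).

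Outside the named genes, 16010 probe sets without a gene name and 1814 with several gave 0 calls for IMQ over all pairs in limma. The unadjusted p was under 0.05 for 1585 and 172 of them.

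Without arm levels, 747 genes passed for IMQ over all 8 arrays, and of the 35 splits of these arrays into 4 and 4, 1 gave as many, the real one; the highest of the others gave 7. For the 747, chance assignment of unpaired arrays thus has a share of 1 in 35, the smallest these splits can give. That is under 0.05 but does not exclude chance. It does not cover the 685 of the fit with arm levels, since exchanging labels within the 4 pairs gives too few assignments for a share under 0.05. For the KO arrays alone, 58 genes passed, 1 of the 10 splits into 3 and 3 gave as many, the real one, and the highest other gave 0; 10 splits are too few for a share under 0.05.

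The first pattern is the intermediate level of genes raised by IMQ on KO_Allo. Over 59 genes higher by 2 log2 units or more with IMQ in the WT, KO plain and KO B pairs, KO_Allo held a median of 15.8% of the rise in the B pair on the linear scale, with quartiles of 7.38% and 27.7%. RNA of IMQ-treated skin mixed into the sample would give all genes about 1 share. The interquartile range over the median was 1.29, against 0.449 on KO_IMQ, but this ratio grows as the median nears 0. On KO_CTRL, without IMQ, the quartiles of the share were -5.84% and 2.09%, a narrower range than on KO_Allo. Krt6b held 53.1% on KO_Allo, where S100a8 held 6.54% and Serpinb3a 4.56%. The range on KO_Allo was wider than on KO_CTRL but narrower than on KO_IMQ, whose quartiles were 97.0% and 155%. Mixed-in skin could itself differ from KO_IMQ_B from gene to gene, so these values cannot exclude mixing. An exchange of the KO_Allo and KO_IMQ_Allo labels is argued against by the same genes, of which 8 of 59 read higher on KO_Allo (median difference -1.21, quartiles -1.91 and -0.32). The exchange was first judged by the share of genes, which left it open, and was put on the median and quartiles after the values were seen. Mixing, or an effect of alloferon itself, of rubbing or wounding, or of 1 unusual skin piece stays open, since there is 1 array.

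The second pattern is the lower level of some genes raised by IMQ on KO_IMQ_Allo. Of the same 59 genes, 7 read lower by 1.5 log2 units or more than on both other KO IMQ arrays: Il1b, Mmp13, Saa3, Tmprss11g, Tmprss11b, Gsta4 and Chil3. The low share of the rise they kept (median 11.8% on the linear scale, against 54.9% over all 59) follows from that choice and sets no standard. The 7 held 1 of the 4 IL-1 and IL-36 genes and 1 of the 5 antimicrobial genes among the 59. Of the others in these lists, Il1f6 held 106%, S100a8 85.6% and Defb3 37.9% of the rise in the B pair on KO_IMQ_Allo. Over members whose mean on KO_IMQ and KO_IMQ_B was at least 2 times the control level, 9 of 13 macrophage genes kept 30.7% (quartiles 13.6% and 38.3%) and 7 of 14 neutrophil genes 29.7% (quartiles 16.9% and 31.9%); that choice itself favours a share under 100%, so with no count of cells and 1 array, fewer cells of either type cannot be told apart from less expression per cell. This test was first run on log2 differences, then on the linear scale, and then under a stricter rule, each revision after values were seen. An action of alloferon is named by the design and stays untested with 1 array.

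The third pattern is the fall of hair follicle genes with IMQ. A shallower piece of tissue on the IMQ arrays would lower muscle and hair genes together. In the KO Allo pair, where muscle genes differed least (-0.51), the hair follicle median was -1.79. In the KO B pair the medians were -0.61 for muscle and -1.97 for hair follicle genes. The arrays without IMQ in both pairs already read low for muscle, with 8.40 on KO_Allo and 8.79 on KO_CTRL-B. WT_CTRL and KO_CTRL read 11.19 and 11.33, and the IMQ arrays 7.84 to 9.30. Muscle may have had little room to fall in these pairs, so a small muscle difference there cannot exclude a difference in depth. A hair cycle stage that differs between skin pieces cannot be told apart from an IMQ effect, because KO_CTRL, without IMQ, read low. Below its hair follicle median of 6.74 lay 3 of the 4 IMQ arrays: WT_IMQ (6.33), KO_IMQ (5.69) and, only just, KO_IMQ_Allo (6.72). KO_IMQ_B read 7.65. The low median of KO_CTRL did not hold alike for all hair genes. In the KO plain pair Krt71 and Tchh changed by -5.07 and -4.72 log2 units, and Krt35 by -1.36. With the hair follicle mean as a covariate 0 genes were called over all pairs, and the median standard error went from 0.112 to 0.472 log2 units.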
